A study of Drosophila melanogaster with 4 samples.

How the data were processed

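Anti-GFP chromatin immunoprecipitation and sequencing was carried out on whole Drosophila melanogaster embryos of 6 to 24 h that express exex fused to GFP at its C-terminus. Per the labels, chromatin was sonicated, fragments were of 200 to 800 bp, and the 4 libraries are biological replicates. All 4 formed 1 group, taken from the source name in the labels, and no sample was left out.

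Peak lists were deposited for each replicate, for the pooled replicates and for the IDR filter, all in narrowPeak format on dm6. Per the file lists deposited with the samples, the replicate and pooled lists were derived from the alignments and 1 further input that all of them share, and the IDR list from the 4 replicate lists and the pooled list. The labels name a possible control experiment, which was not analysed here, and the deposited signal tracks were not used here. The aligner, peak caller and IDR threshold are not given in the sources used here. The authors' signal value of a peak was treated as a score, used only to rank and describe peaks within a list. The deposited q-value of a peak is on a −log10 scale and reaches 1 shared maximum per list, so it was used only to count peaks with q under 0.01. All 7909 IDR peaks were identical to the 7909 highest-signal peaks of the pooled list, so an alternative built on those pooled peaks changes nothing. All 157909 lines of the 6 lists lay on the 6 main chromosome arms and within the chromosome ends of the reference, Drosophila Release 6. Genes came from Ensembl release 115 (BDGP 6.54), with 13945 protein-coding genes and 19607 distinct TSSs on the main arms.

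The 4 replicate lists and the pooled list each had a fixed length of 30000 peaks, so a weaker library fills its list with weaker peaks, and the number of peaks says nothing of enrichment. In replicate 4, 23.2% of peaks had q under 0.01, against 43.1%, 39.6% and 46.2% in replicates 1 to 3. Read depth is unknown. To keep ranks comparable, each replicate was represented by its 7909 highest-signal peaks.

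Replicate support was the share of IDR peaks overlapped by at least 1 bp, with the mean and SD over replicates and no test. Summit location was compared with 1000 sets of random positions with the same number per chromosome, leaving out unknown bases, in a two-sided permutation test whose smallest p is 0.002. TAATTA on either strand within 100 bp of the summit was compared with an equal window centred 1000 bp to the right or left by an exact two-sided McNemar test, and all 2080 sequences of 6 bp were run alike with Benjamini-Hochberg adjustment. The share by signal was tested with Fisher's exact test. For 19 gene groups, genes with a summit in the body or within 5000 bp were counted and compared with 10000 random lists matched on extended length in 20 bins, two-sided, with Benjamini-Hochberg adjustment at 0.05 and a smallest p of 0.0002. Of the group members 521 matched an annotated gene and 1, Dl, did not, since that symbol is shared by more than 1 gene. Intervals for shares are 95% Wilson intervals.

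The genes named were fixed by rule before the data were examined, as were the groups, the tests and most of the other settings. The rule took exex, the gene nearest to each of the 20 strongest IDR peaks, up to 4 members with the strongest summits for each group past the threshold and for the motor neuron group, and up to 2 for every other group. The neighbours of exex, the motor neuron genes without a summit and CTTATC and the other sequences picked from the scan of all 6 bp sequences were chosen after their values were seen, while the scan, TAATTA and TAATTR were fixed in advance.

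The other settings fixed in advance were the upper part of the IDR list by signal, leaving out each replicate, a 50% reciprocal overlap or summits within 100 bp, a 500 bp promoter, a 50 bp motif window, a flank at 2000 bp, TAATTR, distal summits, other signal groups, and other ways to assign summits to genes. Without a replicate, the IDR peaks overlapped by the highest peaks of each of the other 3 were used, since the IDR filter itself was not rerun. The tests were checked on simulated data. With 19 of 20 genes of a list given a peak, 100% of 100 such lists were called among 13945 genes, and 4% of 100 random lists. Summits and list genes were drawn at random there, so neither clusters of genes or peaks nor smaller effects were checked. For the motif test, TAATTA was planted at some of 7909 random positions, which added 8.51 percentage points of positions that had lacked it. The share holding it rose by 8.55 points, which checks the counting but not the comparison with flanks. Of 100 draws of random positions with nothing planted, 4% were called. Random positions do not differ from their flanks in base composition on average, while IDR summits do (median GC 38.8% and 42.8%). The rate of 4% therefore need not hold for IDR summits. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.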

Results

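The series measured where the exex protein sits on the chromosomes of Drosophila melanogaster embryos. exex is the fly homologue of HB9, a homeodomain transcription factor needed for the identity of ventrally projecting motor neurons. Chromatin came from whole embryos aged 6 to 24 h of a line that carries exex with GFP at its C-terminus, and it was precipitated with an anti-GFP antibody. The 4 libraries were labelled as biological replicates of 1 group, with no second condition, so the design allows a comparison between replicates and a description of the bound regions. Each replicate list held 30000 peaks, and the list of peaks that passed the authors' irreproducible discovery rate (IDR) filter held 7909 peaks in 7247 distinct regions. Read depth is unknown, since the peak lists carry no read counts. Peaks with a q-value under 0.01 numbered 12935, 11893, 13846 and 6947 in replicates 1 to 4.

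The replicates were compared to learn which bound regions recurred. Of the 7909 IDR peaks, 5161 were overlapped by the 7909 highest-signal peaks of every replicate, and 11 by those of none. Replicates 1, 2, 3 and 4 recovered 88.8%, 88.1%, 90.1% and 80.1% of the IDR peaks in this way, a mean of 86.8% ± 4.51 (SD, n = 4). In the complete lists of 30000 the mean was 98.0% ± 0.738 (SD, n = 4). Replicate 4 was lowest by either measure. Pairs of replicates without it shared 80.5% to 85.4% of their highest peaks, and pairs with it 74.6% to 79.0%. No peak had the same position and signal in any pair of replicates, so each was counted as a separate sample. The IDR list was made from these same replicates, so their recovery of it is not an independent measure. The recovered share was 67.9% when peaks had to overlap reciprocally by 50%.

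The strongest peaks of every library lay around exex itself (FBgn0041156, chromosome 3L, 7948186 to 7951563, plus strand, dm6). The peak ranked 1 by signal in each of the 4 replicates had its IDR summit at 7942646, in intergenic sequence upstream of the gene. The peak ranked 2 in each replicate had its summit at 7952074, in intergenic sequence just past the 3' end of the gene. Within 20 kb of exex the IDR list held 26 summits, among them 6 of the 20 strongest. When the chromosome arms were divided into 3084 adjacent windows of that size, placed without regard to genes and so including the exex region, none held as many. The highest held 22 and the median window held 1. These are counts of summits, and some summits at exex shared a called region, so they do not count separate regions. At the start of exex, the summits at 7948058 and 7948287 lay in the promoter, and the summit at 7949976 lay in an intron. The annotated neighbours in this window were syd, Srp9, CG43880 and RNaseX25. The expressed transgene carries exex sequence, and its insertion site and copy number are not given in the sources used here.

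**Figure D1:**
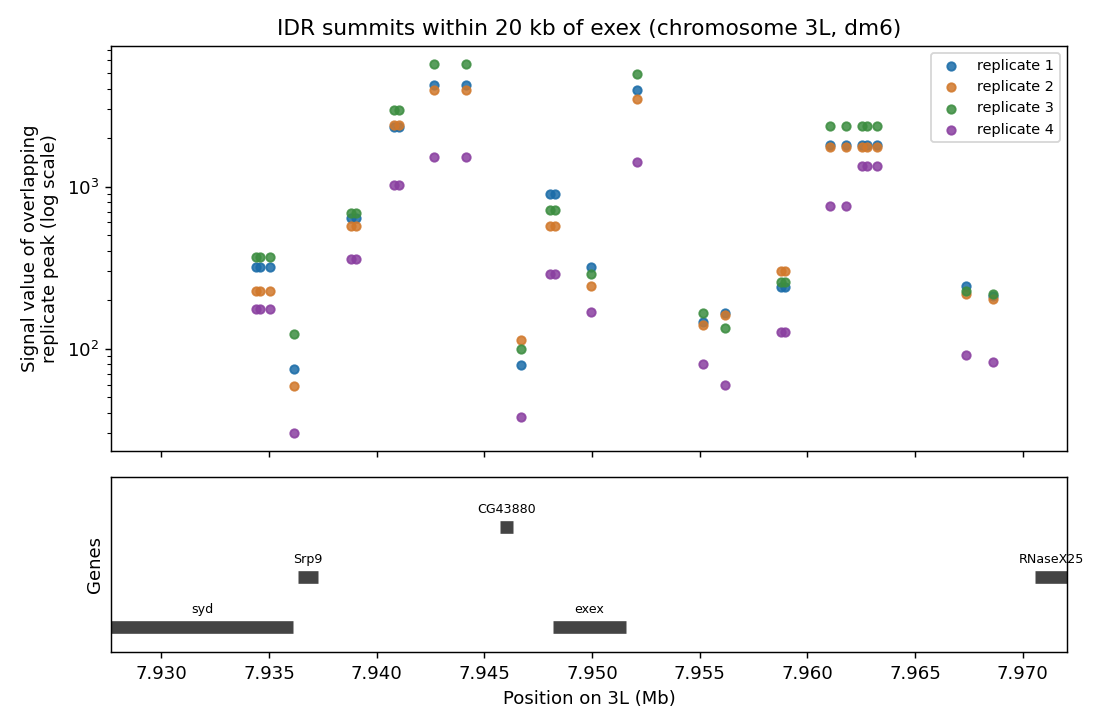
IDR summits within 20 kb of exex on chromosome 3L (dm6, position in Mb), with the signal value of the overlapping peak in each replicate on a log axis (upper panel) and the protein-coding genes of the window, trimmed at its edges (lower panel). Summits that share a replicate peak repeat its value, and the highest points, in all 4 replicates, belong to the peak from 7941963 to 7944592.

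Of the 20 strongest IDR peaks, those outside the exex locus lay mostly at promoters. The 20 peaks had 17 different nearest genes, 11 lay within 1000 bp of a transcription start site (TSS), and all 20 were listed in all 4 replicates with a rank of 50 or better. Replicate ranks are those of the overlapping replicate peak, so summits that share such a peak also share its rank. CG14502 (chromosome 2R, 18288696 to 18294712) had promoter summits at 18290155 and 18289158, ranked 3 and 18. Promoter summits also lay at CG8785, CG6231 and CG3649, and at SNF4Agamma, which encodes the gamma subunit of AMP-activated protein kinase. The same held for the trypsin gene etaTry, with its summit 209 bp from the TSS, and for Diap1, an inhibitor of apoptosis, with its summit 112 bp away. CG8249, CG8093 and alpha-Man-Ib, an alpha-mannosidase gene, completed the promoter group. Summits nearest to Eglp4, of the aquaporin family, and CG11050 lay in introns, and the summit nearest to CG6996 lay in a 3' UTR. The remaining summits, nearest to CG43880, exex, Srp9 (a signal recognition particle subunit) and RNaseX25, were the intergenic ones of the exex locus. The sequence TAATTA occurred within 100 bp of 11 of these 20 summits, and CTTATC within 100 bp of 12.

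IDR summits were concentrated at promoters and nearly missing from coding sequence outside promoters. Within 1000 bp of an annotated TSS lay 4342 of 7909 summits, or 54.9% (Wilson 95% interval 53.8 to 56.0), against 20.4% ± 0.457 (SD) of random positions. The highest peaks of the replicates gave 53.6%, 52.5%, 55.3% and 60.6%, a mean of 55.5% ± 3.58 (SD, n = 4). The two-sided permutation p was 0.002, the smallest that 1000 random sets can give. Coding sequence outside promoters held 0.329% of summits against 10.7% of random positions, and intergenic sequence held 9.22% against 28.4%. Introns held 33.3% against 36.2%, a smaller difference that was about as large as the SD of 2.92 points between replicates. The median distance to the nearest TSS was 792 bp. Intervals cover counting error only.

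**Figure D2:**
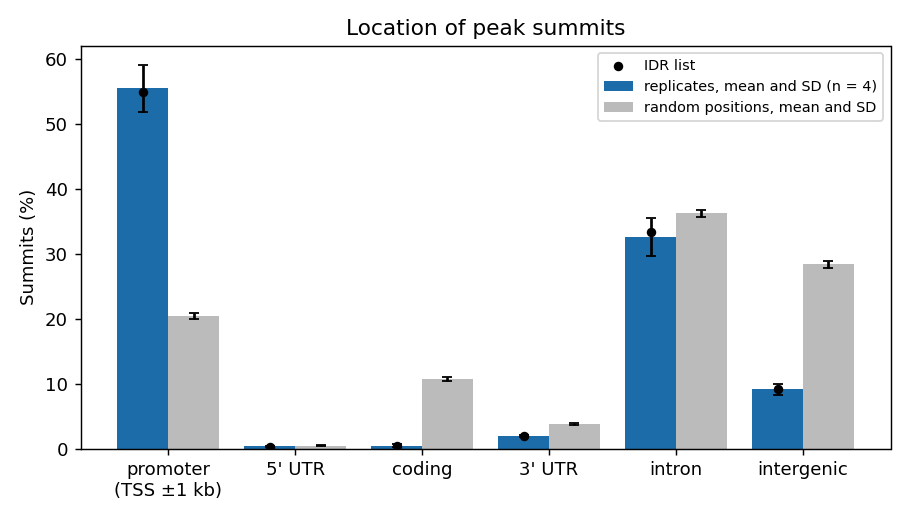
Share of summits or positions (%) in each annotated class, with blue bars for the mean of the 4 replicates, grey bars for the mean of 1000 sets of random positions, error bars for the SD and points for the IDR list. Promoters held 54.9% of IDR summits and 20.4% of random positions, and coding sequence outside promoters held 0.329% and 10.7%.

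The next question was whether summits carried TAATTA, the core site of Antennapedia-type homeodomains such as that of exex. TAATTA lay within 100 bp of 19.7% of IDR summits (Wilson 95% interval 18.8 to 20.6) and in 11.9% of flanking windows (11.2 to 12.7) centred 1000 bp away. The sequence was found only at the summit in 1367 peaks and only at the flank in 753 (exact two-sided McNemar test, p = 5.38e-41). The difference was 7.11 ± 1.22 percentage points over the replicates (SD, n = 4), higher at summits in 4 of 4. Among all 2080 sequences of 6 bp, TAATTA ranked 24 by the test. Median GC content was 38.8% at summits and 42.8% at flanks, and all 36 sequences made only of A and T were more frequent at summits. Among these 36, TAATTA ranked 6 by the test, behind AATTAT, AATTAA and TAATAA among others, and 1 by the ratio of summit to flank share, 1.65. All summits of a list enter these tests, so their p-values describe peaks, not replicates.

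CTTATC, which holds the reverse complement of the GATA core, ranked 1 among the 2080 sequences in the IDR list and in each of the 4 replicates. It lay within 100 bp of 35.4% of summits (Wilson 95% interval 34.4 to 36.5) and in 12.3% of flanks (11.6 to 13.03). It was found only at the summit in 2416 peaks and only at the flank in 587 (exact two-sided McNemar test, p = 1.09e-261, adjusted p = 2.27e-258). The difference was 22.3 ± 2.16 percentage points over the replicates (SD, n = 4), higher at summits in 4 of 4. Farther than 1000 bp from any TSS it was 40.1% against 12.6%. The next sequences, TGATAA, CGATAA and AGATAA, also hold a GATA core and were found at 35.1%, 24.3% and 27.2% of summits. After Benjamini-Hochberg adjustment 503 of the 2080 sequences were more frequent at summits and 788 less frequent. Summits with TAATTA held CTTATC less often than summits without it, at 32.4% and 36.2% (Fisher's exact test, two-sided p = 0.00498).

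**Figure D3:**
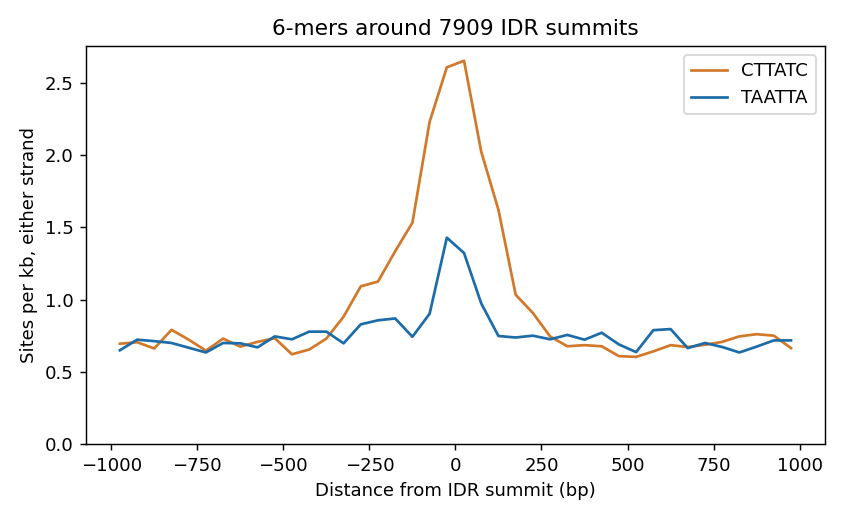
Sites per kb on either strand of CTTATC and TAATTA by distance from the IDR summit (bp, bins of 50 bp), over 7909 summits. In the central 100 bp CTTATC reached 2.63 sites per kb and TAATTA 1.38, against 0.700 and 0.696 beyond 500 bp.

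Both sequences were more frequent at peaks of higher signal. TAATTA lay at 24.1% (Wilson 95% interval 22.3 to 26.1) of the 1977 IDR summits of highest signal and at 17.2% (15.6 to 18.98) of the 1977 of lowest signal (Fisher's exact test, two-sided p = 1.10e-07). The replicate lists gave a difference of 7.03 ± 1.25 percentage points (SD, n = 4), in the same direction in 4 of 4. CTTATC lay at 47.3% and 25.2% of the same summits (Fisher's exact test, two-sided p = 6.57e-48). The promoter share, at 54.1% in each of these groups of summits, showed no such difference.

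Gene groups fixed before the data were examined were then compared with genes of like length, counting a gene if an IDR summit lay in its body or within 5000 bp. Of the 13945 protein-coding genes, 7726 (55.4%) met this. Ribosomal protein genes exceeded their length-matched lists, and chemoreceptor, neuroblast and other homeobox genes fell below theirs, while the remaining 15 of the 19 groups did not pass the Benjamini-Hochberg threshold.

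Summits lay at 64 of 82 ribosomal protein genes, where random lists gave 41.7 (permutation adjusted p = 0.0019). Of these genes 53 had a summit within 1000 bp of a TSS. The strongest summits in the bodies or within 5000 bp were those of RpL40, RpS23, RpL4 and RpL34b, with IDR ranks of 308, 569, 667 and 685. Those of RpL40 and RpS23 lay in intergenic sequence outside the gene, and those of RpL4 and RpL34b in promoters, of these or of other genes. The share was 76.8%, 70.7%, 76.8% and 89.0% in replicates 1 to 4, highest in replicate 4, which had the weakest overlap with the others. Chemoreceptor genes, which act mainly in sensory neurons, had summits at 51 of 179 against 99.6 (permutation adjusted p = 0.0019), with 28.8% ± 1.33 over the replicates (SD, n = 4; permutation test on the IDR list). This call was lost with circular shifts of the summits, at 51 against 55.8 (permutation adjusted p = 0.932), but shifted summits reached 34.0% of all genes against 55.4% observed, which lowers every count of the comparison. The chemoreceptor genes with the strongest summits were Ir68a, Or46a, Ir48c and Gr64c. Each of these summits lay outside the body of the named gene. Those counted for Or46a and Gr64c lay in promoters of other genes and that for Ir48c in an intron of another gene. The summit counted for Ir68a lay in intergenic sequence.

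Neuroblast genes had summits at 3 of 16 against 9.25 (permutation adjusted p = 0.0142). The 3 were vnd, a homeobox gene of ventral neuroblasts, insc and pros, with IDR ranks of 854, 1973 and 2843. Each of these summits lay outside the body of the named gene, that of vnd in an intron of another gene. The peak at pros was listed in 3 of the 4 replicates. Other homeobox genes had summits at 10 of 29 against 18.7 (permutation adjusted p = 0.0114), the strongest at hth, al, mirr and unpg, with ranks of 436, 807, 2144 and 3083. Those counted for mirr and unpg lay outside the gene body. Neither call held without replicate 2, in a list that was also shortened to the 5421 peaks found in each of the other 3 replicates, where the counts were 3 against 7.57 for neuroblast and 8 against 15.5 for other homeobox genes (permutation adjusted p = 0.101 and 0.0557). Neither held with the nearest TSS, at 2 against 4.76 and 6 against 12.1 (0.519 and 0.0950), or with rotations of the gene order, at 3 against 8.86 and 10 against 16.1 (0.145 and 0.313), so the counts stayed below the random lists in each of these.

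Transcription factors of motor neurons, the cells in which exex is best known, had summits at 4 of 8 genes against 5.08 (permutation adjusted p = 0.821). These were Lim3, grn, tup and zfh1, with IDR ranks of 53, 883, 2610 and 3280, and eve, Oli, HGTX and vvl had none. The Lim3 summit lay in an intron at 19097629 of chromosome 2L and ranked 53, 82, 44 and 162 in replicates 1 to 4. Axon guidance genes had summits at 17 of 32 against 21.2 (permutation adjusted p = 0.361), led by Sema1a and fra at ranks 22 and 818. Neurotransmission genes had 11 of 21 against 13.9 (0.499), led by Syx1A and elav. Temporal factors had 2 of 7 against 4.48 (0.310), nub at rank 31 and grh at rank 2302. Glial genes had 9 of 12 against 7.52 (0.821), led by pnt and gcm2. The strongest summits of grn, tup, grh, Syx1A, elav and gcm2 lay outside the body of the named gene.

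Among the other groups, Hox genes had summits at 2 of 8 against 5.35 (permutation adjusted p = 0.147), Antp and Ubx, and the Ubx peak was listed in 2 of the 4 replicates. Segmentation genes had 6 of 15 against 9.35 (0.310), led by hh and hry, and tracheal genes had 2 of 8 against 5.14 (0.195), bnl and trh. Muscle and mesoderm genes had 11 of 19 against 12.1 (0.895), led by Mef2 and mbc. Endoderm and gut genes had 7 of 10 against 6.51 (1), led by bowl and the GATA factor gene srp, and hemocyte and fat body genes had 7 of 10 against 6.55 (1), led by ush and Hml. Epidermis and cuticle genes had 5 of 10 against 6.45 (0.821), led by sha and knk, and signalling genes had 8 of 11 against 7.27 (1), led by spi and tkv. Proteasome genes had 19 of 32 against 17.1 (0.821), led by Rpn8 and Rpn9, with 50%, 56.2%, 62.5% and 78.1% in replicates 1 to 4. Chorion and yolk genes had 4 of 12 against 5.98 (0.659), led by Yp3 and Cp36. The strongest summits of Ubx, hry, bnl, Mef2, srp, Hml, sha, knk, spi, Rpn8, Rpn9, Yp3 and Cp36 lay outside the named gene. Those of Hml and knk lay within another gene. With few members in most groups, a p over the threshold does not show that a group was bound like other genes.

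**Figure D4:**
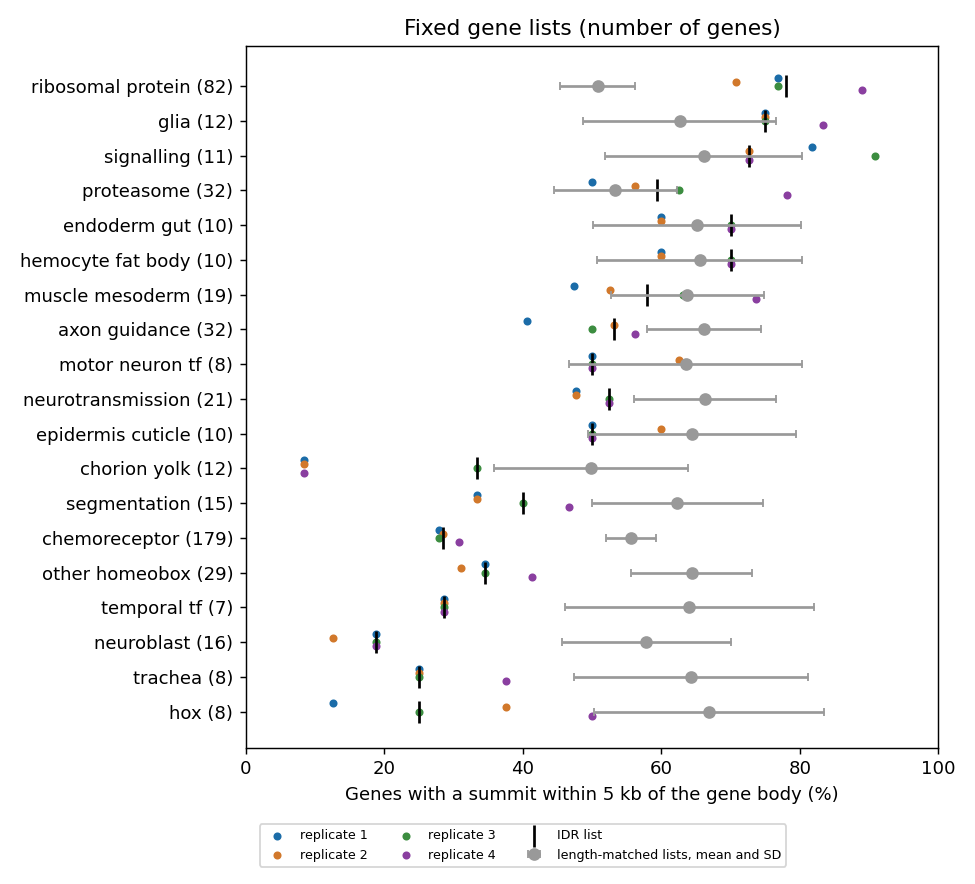
Share of genes (%) in each fixed group with a summit within 5 kb of the gene body, for the IDR list (black bars) and 4 replicates (points), with the mean and SD of length-matched random lists (grey); the number of genes is in parentheses. Ribosomal protein genes, at 64 of 82, lie above their random lists, and chemoreceptor genes, at 51 of 179, lie below.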

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

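The test on chromosome 4 was chosen only after the result was seen. Of 26 measures compared over the 4 replicates, 7 had a replicate far from the others. In 6 of the 7 the other 3 replicates were equal, so that a difference of 1 gene is enough, and the rate of about 1 in 20 that chance gives for measured values does not apply to them.

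Replicate 4 listed 496 peaks on chromosome 4 among its 30000, against 26, 28 and 60 in replicates 1 to 3. A candidate explanation is that weaker enrichment let background fill the end of a list of fixed length. Chromosome 4 held 0.556% of the 7909 highest peaks of replicate 4 and 2.05% of the peaks below them (odds ratio 3.73, Fisher's exact test, p = 6.94e-23). Those highest peaks already held 44 on chromosome 4, more than the complete lists of replicates 1 and 2 and fewer than that of replicate 3. In replicate 4 only 6947 peaks had q under 0.01, so its 7909 highest peaks may also include background, and these 44 do not decide. Of the chromosome 4 peaks of replicate 4, 9.48% were overlapped by a peak of another replicate, against 70.4% of its other peaks. Why background would favour this chromosome stays open. The design gives 1 group, so no biological explanation was tested.

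The other 6 measures rest on 1 to 3 genes. In replicate 2, 62.5% of motor neuron factors had a peak against 50% in each other replicate, 12.5% of neuroblast genes against 18.8%, and 60% of epidermis and cuticle genes against 50%. In replicate 4, 83.3% of glial genes had a peak against 75%, and 37.5% of tracheal genes against 25%. In replicate 3, 33.3% of chorion and yolk genes had a peak against 8.33%.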

How the results depend on the processing

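The alternatives with 1 summit per region, without 20 kb on each side of exex, with circular shifts of the summits and with rotations of the gene order, and all those run for CTTATC and for the rank of the exex peak, were chosen after seeing the data. Replicate support moved from 86.8% to 98.2% in the part of the IDR list with the highest signal, to 67.9% with a 50% reciprocal overlap and to 78.9% with summits within 100 bp, and ranged from 85.7% to 89.0% without 1 replicate. The promoter share, the TAATTA difference and its relation to signal kept their direction and side of the threshold in every alternative run; without 1 replicate they ranged from 52.8% to 55.4%, from 6.77 to 8.40 and from 7.36 to 9.82 percentage points. The count of 4 gene groups past the threshold ranged from 2 (without replicate 2) to 6 (without replicate 4). It was 2 with the nearest TSS, 2 with circular shifts and 2 with rotations, and it was 6 in the highest-signal part of the list. Circular shifts are badly calibrated, since shifted summits reached 34.0% ± 1.14 (SD, 100 shifts) of all genes against 55.4% observed, which favours any excess of genes and ends calls of fewer genes, so no call is read from them. Over the other 12 alternatives the ribosomal and chemoreceptor calls were lost in 0, other homeobox in 4 and neuroblast in 5; the cause was not tested. The settings without 1 replicate also shorten the list, to between 5339 and 5982 of 7909 peaks, so the loss without replicate 2 cannot be put down to that replicate alone. Direction was read only for called groups, and none of them reversed. Among groups not called, 17 values changed sign and 7 values passed the threshold in these 12 alternatives. Read depth is unknown, so what it limits was not analysed here.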

Other observations

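The families below and their comparison with rotations of the gene order, and with genes used in every cell, were chosen only after the result was seen.

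Among 90 gene families of at least 8 genes, taken from symbols, 16 differed from length-matched lists and 10 of these also from rotations of the gene order, which keep neighbouring genes together; the Cpr genes entered under a symbol stem and again under a pattern. The counts and p-values here are set against the mean over rotations. Mitochondrial ribosomal protein genes had summits at 56 of 73 against 40.4 (permutation adjusted p = 0.0129), with 55, 50, 54 and 63 in replicates 1 to 4. Fewer genes had summits among the Or odorant receptors, 8 of 59 against 32.7 (0.00645), and the other chemoreceptor families had 21 of 60 Ir genes (0.135) and 22 of 60 Gr genes (0.230) against 33.2 for each. Against length-matched lists the Ir and Gr genes were also fewer (permutation adjusted p = 0.0040 and 0.0405), and the difference from the Or genes was not tested. Fewer also had summits among the Obp odorant-binding proteins, 12 of 51 against 28.3 (0.0129), and the Cpr cuticle proteins, 20 of 70 against 38.8 (0.0194). Histone genes had 2 of 115 against 63.7 (0.00645); most lie in a repeated cluster, where reads are hard to place. Osi genes had 2 of 25 and Twdl genes 3 of 25, against 13.9 for each, and neither passed (0.229 and 0.110). Both were fewer against length-matched lists (permutation adjusted p = 0.0026 and 0.0040). Rotations are not matched on gene length, and length-matched lists gave 40.1 for the histone genes.

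In 4 families of digestive enzymes and glutathione transferases, picked because their counts came out high, nearly every gene carried a summit, while other families of hydrolases did not pass the test: lipases had 8 of 12 against 7.15 and the Ser and SP proteases 4 of 8 against 4.50 (adjusted permutation p = 1 for each). Summits lay at 11 of 11 trypsin genes, 16 of 16 Jonah protease genes, 10 of 10 maltase genes and 34 of 35 glutathione transferase genes, against 4.91, 7.24, 5.80 and 17.1 in length-matched lists (permutation adjusted p = 0.00720, 0.00257, 0.0530 and 0.00257 over all families), so the maltases missed the threshold. Neighbouring genes can share peaks: rotations that keep tandem clusters gave as many trypsin and maltase genes too often to set these apart (adjusted p = 0.388 for each), but not Jonah protease (0.0439) or glutathione transferase genes (0.0129), while circular shifts (permutation p = 0.002, the smallest they can give) decide nothing, since they reached 34.0% of all genes against 55.4% observed. That peaks arise at any strongly transcribed gene stays open, since proteasome, ATP synthase and NADH dehydrogenase genes together lay at 1.06 times their length-matched lists, but both kinds of ribosomal protein genes exceeded theirs and no expression was measured. A candidate explanation is that regions with GATA sites were bound or recovered: 50 of 96 summits at these genes held CTTATC (odds ratio 2.00, Fisher's exact test, p = 0.000813) where 35.2 were expected from summits of like signal, but summits at ribosomal protein genes, which also carried more peaks, held it less often than others (39 of 161, odds ratio 0.577, Fisher's exact test, p = 0.00262), so it would not account for those.

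The strongest peaks of every library lay at exex. Binding at homeodomain core sites could contribute, but 6 of 26 summits there held TAATTA (odds ratio 1.22, Fisher's exact test, p = 0.624), too few to decide. Extra copies of the locus in the tagged line may also raise the signal. The median signal at the locus was 1.79 times that of the other IDR peaks, but peak lists hold no coverage between peaks, so this cannot be told apart from binding. That median does not describe the strongest peaks. The highest signal there was 129, 114, 148 and 60.5 times the list median in replicates 1 to 4. Copy number was not measured, so how much of these values it could account for is not known. The design gives no untagged line, and no biological explanation was tested beyond the core site.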
